A study of Mus musculus with 6 samples.

How the data were processed

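Total RNA from 6 JB6 samples, 3 labelled HLF and 3 labelled vector, was hybridised to Affymetrix arrays, 1 array per sample. Per the labels' protocols, the cells were stably transduced by a retroviral packaging system, selected with puromycin and harvested while cycling and preconfluent, and biotin-labelled cRNA was made from oligo-dT primed cDNA. The labels also state that HLF protein was checked by western blot. The deposited values are log2 expression values made with RMA, per the submitters' processing notes; its version and options are not given in the sources used here. RMA subtracts background, equalises the distribution of probe intensities between arrays and summarises each probe set, so it holds array totals equal, compresses differences near background and gives no detection call. That the scale is log2 was taken from the values, which ran from about 1.53 to 14.1 with medians of 6.02 to 6.06. No scanner files, scan dates or batches were used here, so batch could not be tested.

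The samples were grouped by their labels. Of 22690 probe sets, 64 were array controls and were left out of the tests. A table of the platform's annotation listed 1 gene symbol for 20380 probe sets, several for 691 and none for 1555. For 20351 of the single-gene probe sets the Entrez ID was found in a RefSeq gene table of assembly GRCm38.p6, which changed 0 symbols and which served only for names, chromosomes and the order of neighbouring genes. Each of 12393 genes was represented by its single-gene probe set with the highest mean over the 6 arrays, and 4956 genes had more than 1 such probe set. Some members of the gene lists are not analysed here.

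Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, 4 residual degrees of freedom, Benjamini-Hochberg adjusted p under 0.05 over all genes), without a filter on dim genes and without the replicate number as a block. A second count required at least a 1.5-fold change. The 32 gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists. HLF replicates 2 and 3 were set against HLF replicate 1 in a 3-group fit. An exact permutation test of 3 against 3 samples cannot go below a two-sided p of 0.1. Arrays of the same group shared at most 82 identical values, so none was treated as a copy of another, and their differences had a SD of 0.157 to 0.181, against 0.559 to 0.575 between groups.

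The grouping, the tests, the gene lists, the rule for named genes and all alternatives but the removal of chromosome medians were fixed before the data were examined. The rule named Hlf, Dbp, Tef, Nfil3, Per1, Per2, Bcl2, Bcl2l1 and Lmo2 always, then the 10 largest rises and 10 largest falls past the threshold with no overlap between the groups, and from each list up to 2 rising and 2 falling members past the threshold. It further allowed the 3 largest rises and falls between HLF replicates 2 and 3 and HLF replicate 1 past the threshold, of which there were 0, and up to 15 genes in the closing section chosen after their values were seen. Beyond the rule, the text names Cdkn1a, Mdm2 and Ccng1 of the p53 targets, genes of the contractile list, the probe set shared by Isg15 and Gm9706, and the 5 genes past the threshold between HLF replicates with an intensity trend. The lists covered PAR bZIP factors and their described targets, the core clock, apoptosis inhibitors, the pro-apoptotic BCL2 family, death receptors, caspases, p53 targets, DNA repair, proliferation, interferon-stimulated genes, MHC class I presentation, NF-kB targets, AP-1 genes, antioxidant genes, the unfolded protein response, cholesterol and fatty acid metabolism, glycolysis and hypoxia, oxidative phosphorylation, matrix genes, matrix proteases, TGF-beta targets, growth factors, lysosome and autophagy, ribosomal proteins, reference genes and markers of keratinocytes, fibroblasts, leukocytes, endothelium and hepatocytes. Some genes stand in 2 lists, such as Birc5, Fas, Bbc3 and Apaf1.

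Alternatives were the replicate number as a block, median centring, quantile normalization of the deposited values, genes under the 40th percentile of mean signal left out, an intensity trend with robust settings, array weights, the mean of all probe sets of a gene, every probe set on its own, each array left out in turn, HLF replicate 1 alone against the arrays labelled vector, adjusted p thresholds of 0.01 and 0.1, camera with an estimated correlation or on ranks, and fry. The code was tested on simulated arrays with the spread of the real ones, in which 200 of 12393 genes were changed. It recovered 48% of 1.25-fold, 74% of 1.5-fold, 100% of 2-fold and 100% of 4-fold changes (50 genes each) and called 11 of 12193 unchanged genes. Of the 32 lists it called the 1 that had been shifted. The simulated genes varied independently of each other, so this says nothing about camera calls on lists of correlated genes. In the real data 42.7% of genes were called, far more than were changed in the simulation, so the recovery rates may differ there. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.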

Results

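JB6 cells, a mouse line derived from epidermis, carried either a retroviral vector with the human HLF gene or the same vector without it, and their transcripts were measured on Affymetrix arrays of 22690 probe sets. HLF, hepatic leukemia factor, is a transcription factor of the PAR bZIP family, whose other members are DBP and TEF and whose levels follow the daily clock in several tissues. The study's title links HLF to the clock and to resistance to cell death, and the comparison asks which transcripts differed in cycling, preconfluent cultures. Each group held 3 samples of total RNA on 1 array each, and the number of arrays limits the precision. Array medians lay between 6.02 and 6.06 (log2). Across probe sets, which are not independent replicates, arrays of the same group correlated at r = 0.998 and arrays of different groups at r = 0.975 to 0.976. The labels do not say that the replicates came from separate cultures or transductions. P-values therefore measure the spread between these samples, which may be technical, and the comparison includes any other difference between the 2 stably selected cell populations. A gene's change is given as the mean of the arrays labelled HLF minus the mean of the arrays labelled vector on the log2 scale, ± the standard error of the limma fit, with n = 3 in each group. Levels are RMA log2 values ± SD.

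The signal of both mouse Hlf probe sets was lower in the arrays labelled HLF. The brighter probe set went from 6.64 ± 0.03 to 4.30 ± 0.18, a change of -2.35 ± 0.09 with a limma adjusted p of 2.3e-06. The other Hlf probe set fell from 6.15 ± 0.10 to 4.53 ± 0.36, a difference of -1.62 with a limma adjusted p of 2.71e-04 among all probe sets. The introduced gene is human and the arrays carry mouse sequences, so neither probe set is known to read it, and the introduced gene could not be used here to check the labels. Groups are therefore called the arrays labelled HLF and the arrays labelled vector. Among the relatives of Hlf, Dbp differed by 0.13 ± 0.05 (adjusted p = 0.0845), Tef by -0.18 ± 0.07 (adjusted p = 0.0634) and Nfil3, a repressor that binds the same DNA element, by 0.33 ± 0.13 (adjusted p = 0.0875). None of these 3 passed the threshold over all genes, and Dbp passed in 1 of 15 alternatives, without dim genes (adjusted p = 0.039, in a range to 0.449). In this list of 4 PAR bZIP factors and NFIL3, 0 members rose and 1 fell at a median of -0.03 (camera adjusted p = 0.791), and adjusted over the list alone 2 rose and 2 fell. Tef passed in 8 of 15 alternatives, with adjusted p from 0.00158 to 0.324, and it did so without HLF replicate 3 (-0.25, adjusted p = 0.00775). Nfil3 passed in 5 of 15, with adjusted p from 0.0121 to 0.656, and it did so without HLF replicate 1 (0.47, adjusted p = 0.0121), while without HLF replicate 3 the difference was 0.19.

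Cadherin-11 (Cdh11), a mesenchymal cell adhesion molecule, showed the largest fall, from 11.4 ± 0.01 in the arrays labelled vector to 2.02 ± 0.19 in the arrays labelled HLF, or -9.39 ± 0.09. Falls were also measured for the secreted matrix proteins Smoc2 (-6.37 ± 0.04), Edil3 (-5.88 ± 0.27) and Sparcl1 (-5.43 ± 0.14), for Glipr1 (-7.58 ± 0.12), for the amine oxidase Aoc3 (-5.61 ± 0.14) and for the peroxidase Gpx7 (-5.51 ± 0.11). The antiviral genes Rsad2 (-5.47 ± 0.05) and Cmpk2 (-5.04 ± 0.16) and the gene Tcim (-5.30 ± 0.05) completed the 10 largest falls. Among the 10 largest rises, Pcolce2, an enhancer of procollagen processing, went from 3.66 ± 0.21 to 10.6 ± 0.03 (6.90 ± 0.10). The microfibril protein Mfap5 rose by 5.54 ± 0.07, the scavenger receptor Scara3 by 5.97 ± 0.09 and Slurp1, a secreted protein of keratinocytes, by 5.65 ± 0.05. Rises were also measured for the homeobox gene Rhox5 (5.75 ± 0.07), the annexin Anxa8 (5.20 ± 0.07), Dpysl3 (4.85 ± 0.06), the aldehyde dehydrogenase Aldh1a7 (4.52 ± 0.14), the prostaglandin E2 receptor Ptger4 (4.18 ± 0.13) and Mfsd6 (4.12 ± 0.15). All 20 genes were picked for an adjusted p under 0.05 and no overlap between the groups, so neither trait is a result. Their limma adjusted p ran from 2.9e-09 to 5.06e-06. In Cdh11, Glipr1, Smoc2, Edil3, Aoc3, Tcim, Cmpk2, Pcolce2, Scara3, Aldh1a7, Ptger4 and Mfsd6 the lower group lay under 3.98, the 25th percentile of the mean signal of all probe sets. RMA values carry no detection call, so the size of these changes rests on a signal near background.

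**Figure D1:**
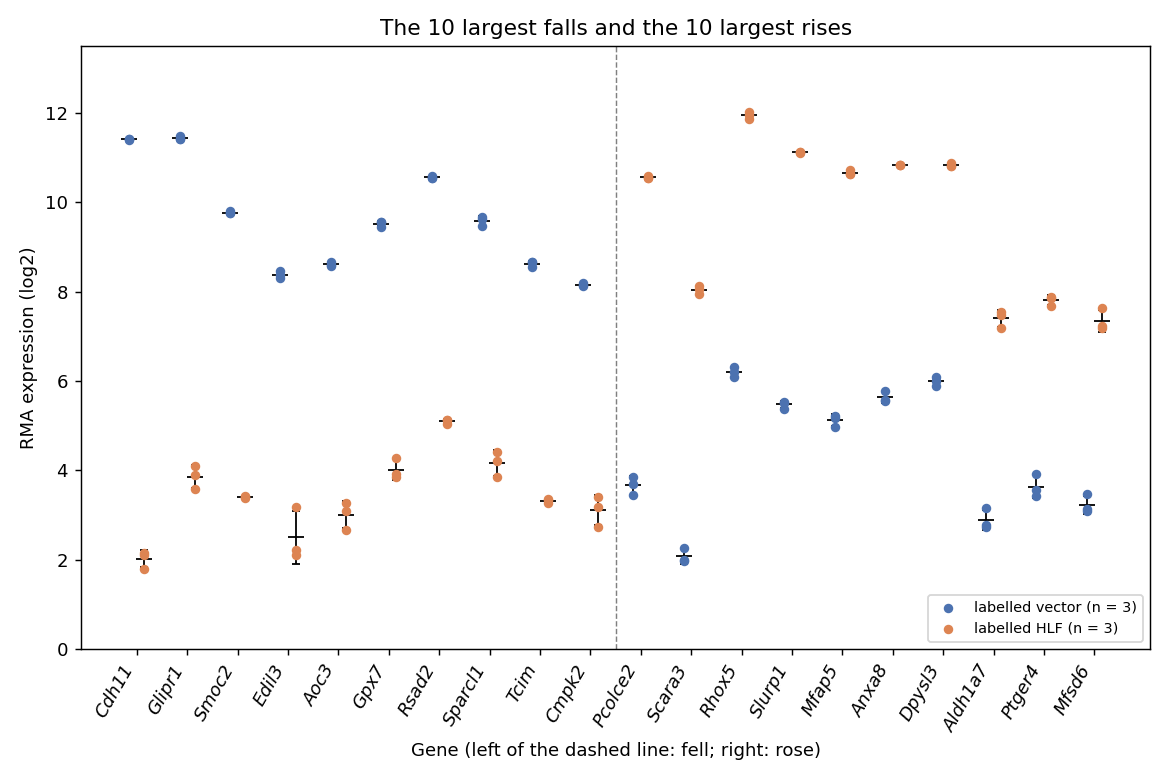
RMA expression (log2, vertical axis) of the 10 genes with the largest fall and the 10 with the largest rise (horizontal axis), 1 point per array, with bars for the mean ± SD of the 3 arrays labelled vector (blue) and the 3 labelled HLF (orange). Cdh11 lies at 11.4 in the arrays labelled vector and at 2.02 in those labelled HLF, and Pcolce2 at 3.66 and 10.6.

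Across 12393 genes, 5298 (42.7%) passed an adjusted p of 0.05 in the limma fit, with 2859 higher and 2439 lower in the arrays labelled HLF. At least 1.5-fold changes were measured for 1681 of them, 978 higher and 703 lower, and at least 2-fold changes for 704, 371 higher and 333 lower. The groups did not overlap in 6550 genes (52.9%), where chance gives 10%. The median absolute change over all genes was 0.16, and the median replicate SD was 0.08. When every probe set was tested on its own, 8781 probe sets passed. Further properties of the samples moved with the groups and accompanied every gene group described here. The 3' minus 5' signal of the beta-actin control probe sets was 0.25 ± 0.01 in the arrays labelled vector and 0.37 ± 0.01 in those labelled HLF, while that of the Gapdh controls was -0.36 ± 0.03 and -0.38 ± 0.02. Among genes with a mean of at least 6, the median change was -0.33 over 196 genes of chromosome X and 0.34 over 169 genes of chromosome 18. Over all measured genes of these chromosomes, dim ones included, the medians were -0.12 (402 genes) and 0.08 (301 genes).

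Genes of cell proliferation rose together in the arrays labelled HLF. Of 36 measured members, 33 rose and 1 fell, with a median change of 0.90, and adjusted over the list alone 34 rose and 1 fell. Ccne2 and Ccna2, cyclins of the start and course of DNA replication, rose by 1.96 ± 0.10 and 1.73 ± 0.05. Birc5, which encodes survivin and belongs to this list and to the apoptosis inhibitors, rose by 1.36 ± 0.05. Rrm1, the large subunit of ribonucleotide reductase, was the member that fell (-0.14 ± 0.04, adjusted p = 0.037). That call was lost without vector replicate 2 (-0.13), vector replicate 3 (-0.13), HLF replicate 1 (-0.14), HLF replicate 2 (-0.15) or HLF replicate 3 (-0.14). The list passed limma's camera test with its preset correlation (adjusted p = 1.57e-13), and not with an estimated correlation (adjusted p = 0.432).

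Interferon-stimulated genes fell in the arrays labelled HLF: 22 of 25 measured members fell and 1 rose, with a median change of -1.53. Adjusted over the list alone, 23 fell and 1 rose. Rsad2, which encodes the antiviral protein viperin, fell from 10.6 ± 0.03 to 5.09 ± 0.05 (-5.47 ± 0.05), and Usp18, which removes ISG15 from proteins, fell by 3.22 ± 0.08. Ifit2, itself an interferon-induced gene, rose by 1.73 ± 0.06, against the direction of the list. Camera with its preset correlation gave an adjusted p of 3.53e-10, and the adjusted p was 0.561 with an estimated correlation. In the related list of antigen presentation by MHC class I, 6 of 11 measured members fell and 2 rose, with a median of -0.39, and adjusted over the list alone 7 fell and 2 rose. The immunoproteasome subunits Psmb8 (-1.59 ± 0.11) and Psmb9 (-1.45 ± 0.08) fell. The class I heavy chains H2-D1 (0.79 ± 0.05) and H2-K1 (0.30 ± 0.05), near-identical paralogs whose probe sets can share signal, rose. This list's call was narrow, with a camera adjusted p of 0.0465 and an adjusted p of 0.667 with an estimated correlation. It was lost in 10 of 17 alternatives (adjusted p from 0.021 to 0.667), among them without vector replicate 2 (adjusted p = 0.0538), vector replicate 3 (0.0533), HLF replicate 1 (0.0677) or HLF replicate 3 (0.0522).

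**Figure D2:**
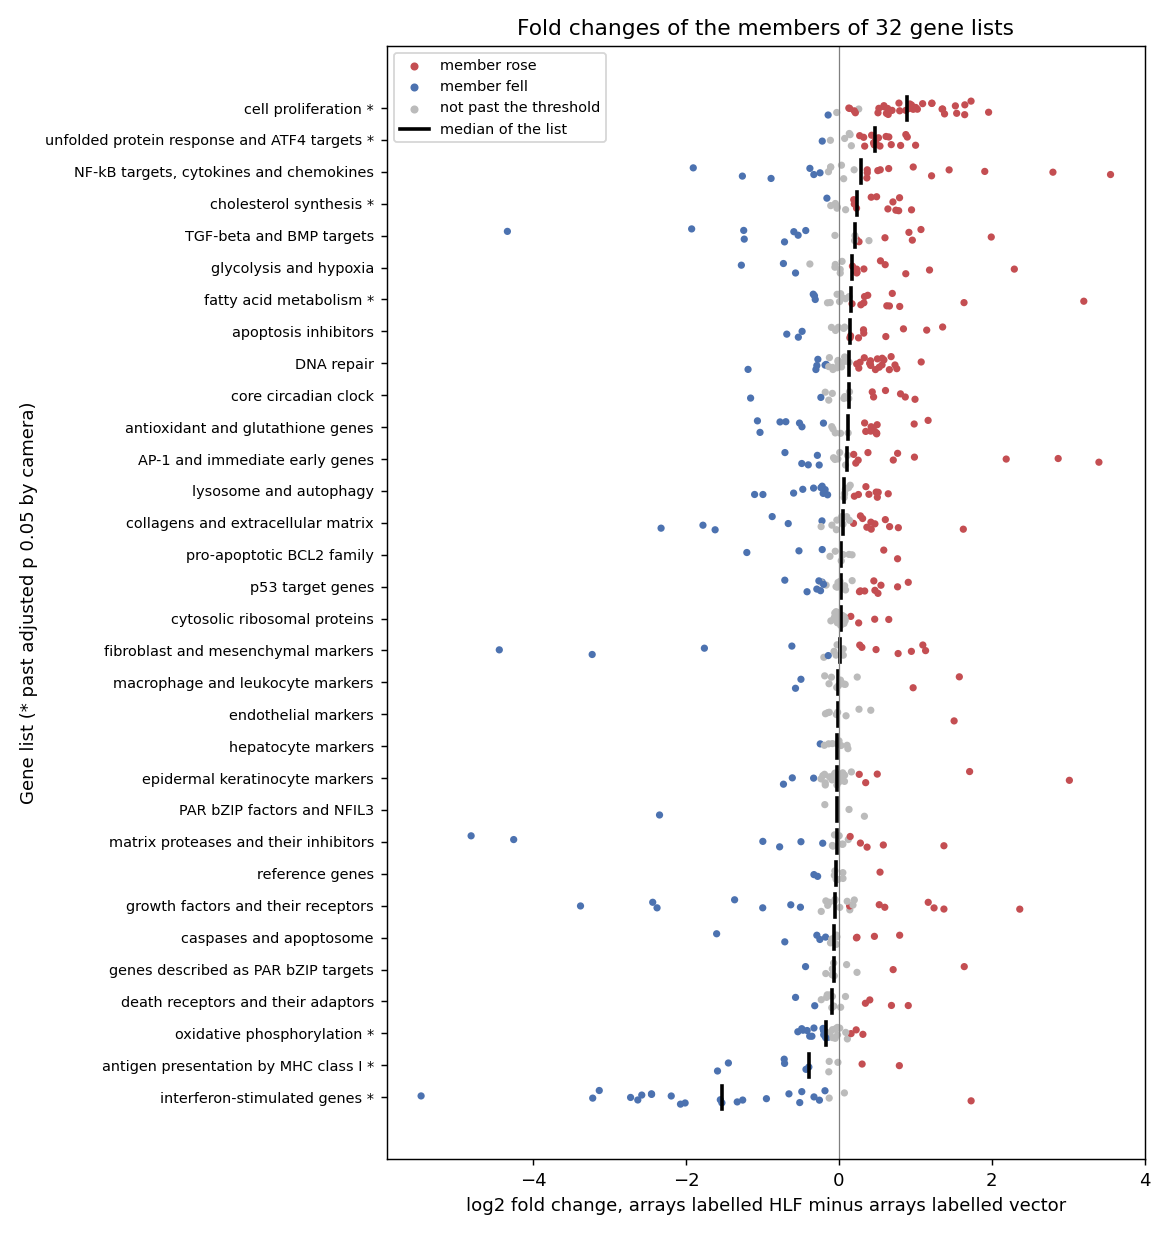
Log2 fold change (horizontal axis, arrays labelled HLF minus arrays labelled vector) of each measured member of 32 gene lists (vertical axis, ordered by median), 1 point per gene, red where the member rose, blue where it fell and grey where it did not pass adjusted p 0.05, with a black bar at the list's median. Cell proliferation lies at the top with a median of 0.90, and interferon-stimulated genes at the bottom with -1.53.

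Genes of the unfolded protein response and targets of ATF4 rose in the arrays labelled HLF, 19 of 25 with 1 falling, at a median of 0.47 (adjusted over the list alone, 20 rose and 1 fell). Sdf2l1, a protein of the endoplasmic reticulum, rose from 6.66 ± 0.05 to 7.66 ± 0.11 and asparagine synthetase (Asns) by 0.89 ± 0.04, while Phgdh, the first enzyme of serine synthesis, fell by 0.22 ± 0.05. The camera adjusted p was 7.06e-07, and the adjusted p was 0.432 with an estimated correlation. Of 17 measured genes of cholesterol synthesis, 11 rose and 1 fell, with a median of 0.23. Fdps, which makes farnesyl diphosphate, rose by 0.95 ± 0.04 and the sterol carrier Stard4 by 0.79 ± 0.07. The sterol isomerase Ebp, on chromosome X, fell (-0.16 ± 0.04, adjusted p = 0.0192), and its direction turned to 0.17 when the median of each chromosome was removed. The call of Ebp was also lost without vector replicate 1 (-0.15), vector replicate 3 (-0.16) or HLF replicate 1 (-0.14). For cholesterol synthesis the camera adjusted p was 0.00991, and the adjusted p was 0.667 with an estimated correlation. Without dim genes it was 0.0604, in a range from 3.19e-05 to 0.667 over the alternatives.

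In fatty acid metabolism 11 of 22 measured members rose and 3 fell, at a median of 0.15, and adjusted over the list alone 11 rose and 4 fell. Lipoprotein lipase (Lpl) rose from 8.67 ± 0.16 to 11.9 ± 0.02 (3.20 ± 0.08) and the desaturase Scd1 by 1.64 ± 0.05, while the fatty acid binding protein Fabp5 fell by 0.32 ± 0.04. The fatty acid transporter Cd36 was measured near background and fell by 0.34 ± 0.11 (adjusted p = 0.0423). The call of Cd36 was lost in 9 of 14 alternatives (adjusted p from 0.00751 to 0.312), among them without vector replicate 1 (-0.33), vector replicate 2 (-0.30), vector replicate 3 (-0.38), HLF replicate 1 (-0.33) or HLF replicate 3 (-0.23). The value shrank most, to -0.12, with the mean of its probe sets, and to -0.22 with chromosome medians removed. The list's camera adjusted p was 0.0405, and the adjusted p was 0.667 with an estimated correlation. Its call was lost in 7 of 17 alternatives (adjusted p from 0.0224 to 0.667), among them without vector replicate 3 (0.0533) or HLF replicate 2 (0.0697). Oxidative phosphorylation went the other way, with 16 of 29 measured members falling and 3 rising at a median of -0.17 (adjusted over the list alone, 17 fell and 3 rose). Cox6c (-0.54 ± 0.04) and Ndufb8 (-0.49 ± 0.04), subunits of complexes of the respiratory chain, fell, and Ndufv1 (0.31 ± 0.05) and Atp5b (0.23 ± 0.05) rose. Camera gave an adjusted p of 0.00991 and, with an estimated correlation, an adjusted p of 0.822. With HLF replicate 1 alone against the arrays labelled vector, 10 members fell and 1 rose. In glycolysis and hypoxia 10 of 19 rose and 3 fell at a median of 0.18, which did not pass camera (adjusted p = 0.202). Adrenomedullin (Adm) rose by 2.29 ± 0.07 and Ddit4 by 1.18 ± 0.04, and Vegfa (-1.28 ± 0.09) and Pfkfb3 (-0.73 ± 0.10) fell.

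Genes that act on cell death changed in both directions. Of 18 measured apoptosis inhibitors 9 rose and 3 fell, with a median of 0.14 and a camera adjusted p of 0.216. Birc5 rose by 1.36 ± 0.05 and Naip2 by 1.15 ± 0.04, while Xiap (-0.68 ± 0.05), which binds caspases and lies on chromosome X, and Birc3 (-0.53 ± 0.06) fell. With HLF replicate 1 alone against the arrays labelled vector 5 of these inhibitors rose and 3 fell, and 5 rose without vector replicate 1 or with chromosome medians removed. Bcl2, the founding inhibitor of its family, differed by 0.14 ± 0.10 (adjusted p = 0.295), which rested on HLF replicate 1: with that array alone against the arrays labelled vector Bcl2 passed (0.33, adjusted p = 0.0317, in a range from 0.0317 to 0.677), and without it the difference was 0.04. Bcl2l1, which encodes BCL-XL, rose by 0.32 ± 0.09 (adjusted p = 0.0269). Its call was lost in 7 of 15 alternatives (adjusted p from 0.00248 to 0.138), among them without vector replicate 1 (0.0703), vector replicate 2 (0.0758), HLF replicate 1 (0.0657) or HLF replicate 2 (0.0794). In the pro-apoptotic BCL2 family 2 of 11 rose and 3 fell, at a median of 0.03 (camera adjusted p = 0.885). Bbc3, which encodes PUMA, rose by 0.77 ± 0.08 and Bid by 0.59 ± 0.06, while Bcl2l11 (-1.21 ± 0.07), which encodes BIM, and Bnip3 (-0.52 ± 0.04) fell. Death receptors and their adaptors had 4 of 15 higher and 2 lower (median -0.09, camera adjusted p = 0.885), with rises of Fas (0.91 ± 0.09) and Cradd (0.69 ± 0.07) and falls of Tnfrsf25 (-0.57 ± 0.10) and Ripk3 (-0.32 ± 0.06). Without HLF replicate 2, or with chromosome medians removed, 4 of these members fell. Among caspases and the apoptosome 4 of 15 rose and 5 fell, at a median of -0.06 (camera adjusted p = 0.728). Casp6 (0.79 ± 0.06) and Casp4 (0.46 ± 0.06) rose, and the mitochondrial nuclease Endog (-1.60 ± 0.11) and the apoptosome scaffold Apaf1 (-0.71 ± 0.05) fell.

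Of 26 measured p53 target genes 9 rose and 7 fell (median 0.03, camera adjusted p = 0.728), and adjusted over the list alone 10 rose and 7 fell. Fas and Bbc3 were again the largest rises, and Apaf1 and the damage-binding gene Ddb2 (-0.42 ± 0.10) the largest falls. DNA repair genes rose more often than they fell, 19 against 6 of 39, with a median of 0.13 and a camera adjusted p of 0.0661. Prkdc, the catalytic subunit of DNA-dependent protein kinase, rose by 1.08 ± 0.11 and DNA ligase 1 (Lig1) by 0.76 ± 0.05. Xrcc5 (-1.19 ± 0.07) and Xrcc6 (-0.30 ± 0.05), the Ku proteins that partner with that kinase, fell. The DNA repair list passed in 3 of 17 alternatives (adjusted p from 0.0126 to 0.832), namely without HLF replicate 1 (0.0466), with the mean of all probe sets (0.0491) and with chromosome medians removed (0.0126).

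Clock genes also went both ways, 6 of 15 higher and 2 lower, at a median of 0.13 (camera adjusted p = 0.216). Bhlhe40, a repressor in the clock, rose by 0.99 ± 0.05 and Per3 by 0.87 ± 0.08, while Per2 (-1.16 ± 0.18, adjusted p = 0.00168) and the kinase gene Csnk1e (-0.24 ± 0.05) fell. The call of Csnk1e was lost with chromosome medians removed (-0.14, adjusted p = 0.0535, in a range from 1e-04 to 0.0535). Per1 differed by 0.14 ± 0.07 (adjusted p = 0.162), and by 0.08 without vector replicate 3. In the list of genes described as targets of PAR bZIP factors 2 of 10 rose and 1 fell, at a median of -0.07 (camera adjusted p = 0.821). The drug efflux pump Abcb1b rose by 1.64 ± 0.06 and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, by 0.71 ± 0.10 from a low level of 4.32 ± 0.14, while pyridoxal kinase (Pdxk) fell by 0.44 ± 0.09. The call of Pdxk was lost with the mean of its probe sets (-0.15, adjusted p = 0.151, in a range from 2.32e-04 to 0.151). Lmo2, near background, differed by -0.17 ± 0.14 (adjusted p = 0.392), a value that rested on HLF replicate 2, since it was 0.00 without that array.

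Inflammatory and immediate early genes held some of the larger changes without passing as lists. Of 24 NF-kB targets, cytokines and chemokines 12 rose and 6 fell, at a median of 0.28 (camera adjusted p = 0.197). The acute phase gene Saa3 rose by 3.55 ± 0.11 and Il6 by 2.80 ± 0.14 from a near-background 3.04 ± 0.27, while the chemokine Ccl5 fell by 1.91 ± 0.11. The adhesion molecule Vcam1 fell on its brightest probe set (-1.26 ± 0.04) and rose on another (0.23, adjusted p = 0.0195). Of 21 AP-1 and immediate early genes 10 rose and 5 fell (median 0.11, camera adjusted p = 0.202). The phosphatase Dusp1 rose from 7.28 ± 0.03 to 10.7 ± 0.05 (3.40 ± 0.05) and Klf4 by 2.87 ± 0.05, and Fos (-0.71 ± 0.06) and Spry4 (-0.49 ± 0.07, to near background) fell. Antioxidant and glutathione genes were split 11 higher to 7 lower among 23 (median 0.12, camera adjusted p = 0.791), and 12 to 7 adjusted over the list alone. The extracellular dismutase Sod3 (1.17 ± 0.05) and Gclm (0.98 ± 0.06), a subunit of the enzyme that starts glutathione synthesis, rose, and Gsta4 (-1.07 ± 0.04) and Hmox1 (-1.03 ± 0.07) fell.

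Genes of the matrix and its turnover changed strongly in single members. Of 28 collagens and extracellular matrix genes 11 rose and 6 fell (median 0.05, camera adjusted p = 0.712). The cross-linking enzyme Lox rose by 1.63 ± 0.04 and Fbln5 by 0.78 ± 0.05, while periostin (Postn, -2.33 ± 0.06) and the collagen Col12a1 (-1.78 ± 0.07) fell. Among 18 matrix proteases and their inhibitors 5 rose and 6 fell (median -0.03, camera adjusted p = 0.791). The proteases Mmp13 (-4.81 ± 0.17, to a near-background 2.81 ± 0.37) and Mmp9 (-4.25 ± 0.11) fell, and the inhibitors Timp3 (1.37 ± 0.05) and Timp1 (0.58 ± 0.05) rose. TGF-beta and BMP targets were split 7 higher to 8 lower among 19 (median 0.20, camera adjusted p = 0.88), and 8 to 8 adjusted over the list alone. Ccn2 (1.99 ± 0.20) and Id1 (1.07 ± 0.05) rose, and the BMP antagonist Grem1 (-4.34 ± 0.12) and Id2 (-1.93 ± 0.07) fell. Growth factors and their receptors had 7 of 25 higher and 7 lower (median -0.05, camera adjusted p = 0.88). The insulin-like growth factor binding proteins went apart, with rises of Igfbp4 (2.36 ± 0.06) and Igfbp7 (1.37 ± 0.04) and a fall of Igfbp5 (-3.38 ± 0.06, to a near-background 3.51), and Igf1 itself fell by 2.44 ± 0.09. Of 25 lysosome and autophagy genes 8 rose and 10 fell (median 0.07, camera adjusted p = 0.885), with rises of Atg12 (0.64 ± 0.07) and Lamp1 (0.51 ± 0.05) and falls of Ctsz (-1.10 ± 0.05) and Npc2 (-0.99 ± 0.05).

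Markers of cell types gave no list past the threshold. Their median levels were 4.18 for epidermal, 3.73 for leukocyte, 3.78 for endothelial and 4.39 for hepatocyte markers, near or under the 25th percentile of 3.98. Fibroblast and mesenchymal markers had a median level of 8.88. Most members of those 4 lists gave little signal, so a flat median says little about the cells' identity. Among 29 epidermal keratinocyte markers 5 rose and 3 fell (median -0.03, camera adjusted p = 0.885), with rises of the basement membrane gene Lamb3 (3.01 ± 0.19) and the integrin Itga6 (1.71 ± 0.06) and falls of Krt10 (-0.73 ± 0.06) and Cldn1 (-0.61 ± 0.13, near background in both groups). With chromosome medians removed, 6 of these markers fell. Fibroblast and mesenchymal markers had 7 of 18 higher and 5 lower (median 0.02, camera adjusted p = 0.885). N-cadherin (Cdh2) rose by 1.13 ± 0.05 and Zeb2 by 1.10 ± 0.17, while the smooth muscle genes Tagln (-4.44 ± 0.14) and Acta2 (-3.23 ± 0.04, to 9.76 ± 0.02) fell. Of 13 macrophage and leukocyte markers 2 rose and 2 fell (median -0.01, camera adjusted p = 0.885), namely Cd14 (1.57 ± 0.07) and Lyz2 (0.97 ± 0.07) upward and Csf1r (-0.57 ± 0.09) and Cd68 (-0.50 ± 0.13, near background) downward. The fall of Cd68 was lost without vector replicate 1 (-0.40, adjusted p = 0.0527, in a range from 0.00333 to 0.174). Of 9 endothelial markers 1 rose, the receptor Tek (1.51 ± 0.13, from a near-background 2.75), and 0 fell (median -0.02, camera adjusted p = 0.88). Without HLF replicate 1, 2 of these markers rose, and without HLF replicate 2, or with chromosome medians removed, 2 rose and 1 fell. Of 9 hepatocyte markers 0 rose and 1 fell, Apoa1 (-0.25 ± 0.06), at a median of -0.02 (camera adjusted p = 0.808). Without HLF replicate 3, or with chromosome medians removed, 2 hepatocyte markers fell, and the call of Apoa1 was lost with HLF replicate 1 alone against the arrays labelled vector (-0.22, adjusted p = 0.138, in a range from 0.00478 to 0.138). Among 22 cytosolic ribosomal proteins 4 rose and 0 fell (median 0.03, camera adjusted p = 0.458), with the largest changes in Rps6 (0.65 ± 0.05) and Rpl14 (0.47 ± 0.05). Of 9 reference genes 1 rose, Hprt (0.54 ± 0.04), and 2 fell, Sdha (-0.33 ± 0.05) and Actb (-0.28 ± 0.04), at a median of -0.04 (camera adjusted p = 0.808). The fall of Sdha, on chromosome 13, was lost with the mean of its probe sets (-0.14, adjusted p = 0.0509) and with chromosome medians removed (-0.11, adjusted p = 0.137), in a range from 2.56e-06 to 0.137.

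Camera with its preset correlation passed 7 of the 32 lists, 4 higher and 3 lower, and 0 lists with an estimated correlation. The fry test, which asks whether a list's genes change without comparing them with other genes, passed 24 lists in one direction and 31 in either direction. For 22 lists the counts adjusted over the list alone equalled those over all genes. The median, the mean and the camera direction differed in sign in 10 lists: genes described as PAR bZIP targets, the pro-apoptotic BCL2 family, death receptors, collagens, TGF-beta and BMP targets, lysosome and autophagy, and the epidermal, fibroblast, macrophage and endothelial markers. With HLF replicate 1 alone against the arrays labelled vector, the rising members numbered 11 in DNA repair, 6 in AP-1 genes, 5 in glycolysis and hypoxia, 3 in matrix proteases, 3 in epidermal markers and 2 in caspases. In that comparison the calls of Atp5b, Pdxk, Phgdh and Zeb2 were lost too.

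The descriptions of HLF replicates 2 and 3 speak of ionizing radiation, while every other label places them with HLF replicate 1, so these arrays were also compared within the group. The p53 target genes, which radiation can induce, had a median of 0.05 in HLF replicates 2 and 3 minus HLF replicate 1, inside the central 95% of matched random lists (-0.00 to 0.08). Camera gave this list an unadjusted p of 0.0191, and of 0.115 with an estimated correlation. Cdkn1a, a p53 target that stops the cell cycle, differed by 0.04 ± 0.06, Mdm2 by 0.00 ± 0.06 and Ccng1 by -0.02 ± 0.08 (standard errors of the limma fit). No gene passed an adjusted p of 0.05 in limma (0 of 12393, smallest adjusted p = 0.751), and 781 had an unadjusted p under 0.05. With an intensity trend and robust settings 5 genes passed, all higher in HLF replicates 2 and 3: Slit2 (0.32 ± 0.04), Fn1 (0.28 ± 0.04), Aebp1 (0.33 ± 0.05), Ltbp2 (0.41 ± 0.06) and Mgp (0.33 ± 0.05). These 5 were chosen after their values were seen. With 1 array on one side the lone array was assumed to vary like the others.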

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

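The count of probe sets without a single gene was planned after the main counts were seen, as were the tests of leukocytes, of exchanged labels, of chromosome medians and of interferon-stimulated genes against random gene sets, while the splits of the arrays and the radiation test were set beforehand. Probe sets that list several genes or no gene take no part in the comparisons of genes, and they too differed between the groups. Of 2246 such probe sets, 108 were at least 1.5-fold higher in the arrays labelled HLF and 95 at least 1.5-fold lower, each past an adjusted p of 0.05 in limma. One of them, shared by Isg15, which encodes an interferon-induced ubiquitin-like protein, and Gm9706, went from 10.1 ± 0.05 to 7.65 ± 0.17, a difference of -2.48, and was chosen after its value was seen.

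Of the 10 splits of the 6 arrays into 3 and 3, 1 gave as many changed genes as the real one, which was the real split itself, with 5298 genes against at most 0 in the others. For genes changed at least 1.5-fold the values were 1681 against 0, and for lists past the threshold 7 against 3. Each count of splits with a result as large was 1, and 10 splits are too few for a share under 0.05. Each other split puts arrays of both labels on both sides, so the difference between the groups enlarges its residual spread. Its low gene counts were therefore to be foreseen and speak for no cause.

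The fall of interferon-stimulated genes in the arrays labelled HLF was weighed against leukocytes in the cultures labelled vector, array scaling and chromosome-wide shifts. Scaling moves genes of the same intensity alike, and the list's median of -1.53 lay below the lowest (-0.35) of 10000 random gene sets matched on mean expression. The list had the lowest median of all lists tested, and the comparison was planned after the main counts were seen. The median absolute change over all genes was 0.16, so that outcome was to be foreseen and is no independent test. The random sets show only that genes of similar intensity did not fall as far as the list. Median centring and quantile normalization left the median of all genes at -0.01 and so tested nothing. The largest chromosome medians, -0.33 on X and 0.34 on 18, were too small to account for the whole fall. Removing each chromosome's median left the list at -1.42, which those sizes had fixed in advance and which is no further test. The labels describe both groups as cultures of the JB6 line selected with puromycin, and so name no source of leukocyte RNA. The leukocyte markers by themselves cannot decide the matter, since they went both ways. Csf1r (-0.57) and Cd68 (-0.50, and -0.40 and no longer called without vector replicate 1) were lower, and Lyz2 (0.97) and Cd14 (1.57) higher. The median change of the leukocyte list was -0.00681 at a median level of 3.73, under the 25th percentile of all probe sets, and decides nothing. An effect of HLF, a lasting difference between the 2 selected cell populations, and a response of the cultures labelled vector to their own vector stay open, and the design cannot separate them.

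The lower signal of mouse Hlf in the arrays labelled HLF was weighed against exchanged group labels. The less changed of the 2 Hlf probe sets differed by -1.62, which exchanged labels could give if it read the introduced human transcript. The labels state that ectopic HLF protein was checked by western blot, which speaks for the labels of the cultures but does not name these RNA samples. No probe set specific to the human gene was used here, so exchanged labels cannot be told apart from a lower level of the cells' own Hlf.

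The p53 targets had a median of 0.0475 in HLF replicates 2 and 3, whose descriptions name radiation, minus HLF replicate 1, inside the central 95% of matched random lists and under the 0.15 that had been set beforehand as a bound against a radiation response. No array here is known to be irradiated, and p53 function in these cells was not measured. The low median therefore speaks against a p53 response at harvest in HLF replicates 2 and 3 beyond that in HLF replicate 1. A response shared by all arrays labelled HLF would not show in this difference. Whether the cells were irradiated cannot be settled.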

How the results depend on the processing

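Of the alternatives in this part, the removal of chromosome medians was chosen only after the results were seen. The count of changed genes ranged from 4624 to 5032 when each array was left out, that of genes changed at least 1.5-fold from 1674 to 1719, and that of lists past camera from 5 to 7. With HLF replicate 1 alone against the arrays labelled vector these counts were 3840, 1633 and 6, and with chromosome medians removed 5528, 1599 and 8. Testing every probe set on its own gave 8781 probe sets past the threshold and 2819 changed at least 1.5-fold, since more features were tested. Of the lists, 4 passed without dim genes, 0 with an estimated correlation, 24 by fry in one direction and 31 in either direction. Fry does not compare a list with other genes. An adjusted p of 0.01 kept 4003 genes and 0.1 gave 6064. HLF replicates 2 and 3 against HLF replicate 1 gave 5 genes with an intensity trend and robust settings and 0 in each of the other alternatives run, and could not be run without HLF replicate 1. Ebp, on chromosome X, went from -0.16 to 0.17 with chromosome medians removed, by the construction of that setting.

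A pairing of the samples by replicate number was neither shown nor excluded. Deviations of same-numbered arrays correlated at 0.01, 0.16 and 0.02, and those of differently numbered arrays at -0.10 to 0.08. With the replicate block 5036 genes passed, 4855 of them also without it, 1682 were changed at least 1.5-fold and 5 lists passed, and 3 endothelial markers rose. Shared calls changed sign in 7 genes with the mean of all probe sets and in 12 with chromosome medians removed, and in 0 under the other settings in which genes were counted. Of the named genes' values under alternatives 1939 kept direction and side of the threshold, 39 lost the call, 15 gained one and 1 reversed. For lists these counts were 516, 23, 3 and 0. The cause was not tested for the lists lost without dim genes. Near background, under about 3.98, RMA values compress a difference, so the size of changes into that range is the least certain.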

Other observations

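The tests of chromosome medians, the random gene orders, the genes in the next sentences and the single contractile genes named were chosen only after results were seen, and the contractile list after the values of 4 other genes, while the bounds of the other tests on chromosomes and of the contractile test were written before those tests were run. The imprinted zinc finger gene Plagl1 fell from 12.1 ± 0.01 in the arrays labelled vector to 7.11 ± 0.14 in those labelled HLF. The imprinted gene Ndn (-2.12 ± 0.14) fell, as did Pawr, a pro-apoptotic gene (-4.81 ± 0.11, to a level near background). The chemokine Cxcl12 (-4.10 ± 0.07), the matrix protein Mgp (-4.97 ± 0.09), the lactate dehydrogenase subunit Ldhb (-4.37 ± 0.07) and the coactivator Ppargc1a (-3.96 ± 0.13, to near background) fell. Rises were measured for Cd34 (3.28 ± 0.05), a surface protein of progenitor cells, Klf2 (3.30 ± 0.07), the receptor Npy1r (2.91 ± 0.07) and, from levels near background, Calcrl (3.55 ± 0.40), Naip5 (3.35 ± 0.09) and Aldh1a1 (2.76 ± 0.14). Naip5 and Naip2 are close paralogs whose probe sets can share signal.

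After the values of Acta2, Tagln, Myl9 (-5.03 ± 0.08) and Cnn1 (-0.04, not past the threshold) had been seen, a list of 18 further contractile genes was written, and 11 of them fell and 2 rose, at a median of -0.52. Camera gave p = 4.5e-05, and the list did not pass with an estimated correlation (p = 0.134). The actin Actg2 (-1.72 ± 0.22), the tropomyosin Tpm1 (-1.59 ± 0.05) and the filamin Flna (-0.89 ± 0.07) fell, while Des rose by 0.44 ± 0.07 and Smtn by 0.41 ± 0.07, and the smooth muscle myosin Myh11, near background, differed by -0.14 and did not pass. A lower level of a contractile gene group is a hypothesis from these data, with no test on other samples. The group is not shown to be one of smooth muscle, since Cnn1, Myh11, Des and Smtn were not called lower.

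Among genes with a mean of at least 6, 15 of 20 chromosomes had a median past an adjusted p of 0.05 against matched random gene sets, 9 higher and 6 lower, with the largest shifts on chromosome X (-0.33, 80.1% of 196 genes lower) and chromosome 18 (0.34, 78.1% of 169 genes higher), followed by chromosome 13 (-0.21 over 243 genes). Over all measured genes, dim ones included, these medians were -0.12, 0.08 and -0.09. The adjusted p of the chromosomes came from random draws of genes, which are not independent replicates, and does not measure the spread between samples. None of the matched random sets reached the -0.327 of chromosome X, so genes of similar intensity did not shift as far. Chromosomes X and 18 were picked for their large medians, so that outcome was to be foreseen and is no independent test. Without genes changed 1.5-fold or more, at least 76.1% of both shifts was left over the remaining 146 and 119 genes. With 80.1% and 78.1% of genes on one side, the sign of these medians could not change by that removal. Only the size left was open, and it shows that strongly changed genes alone did not carry the shifts. A different copy number of whole chromosomes, in either selected population and with or without HLF, stays open as a hypothesis, since no DNA was measured. At least 9 of 10 stretches of neighbouring genes on both chromosomes shared the sign of their chromosome, but so they did in 100% of 1000 random orders of the same genes, so the stretches say nothing about copy number.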
